A study of Sus scrofa with 96 samples.

How the data were processed

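Whole-blood RNA of 24 male Göttingen minipigs was measured on 96 single-colour Agilent porcine arrays, 4 per animal (the day before irradiation and days 1, 3 and 7). Dose, day, animal and batch of every array come from the sample labels, and the animal numbers given there pair the 4 arrays of an animal. The pairing was checked on the values: after removal of the group means, arrays of the same animal on different days had a median correlation of 0.547 (139 of 144 pairs above 0.1), against 0.345 for different animals of the same batch and -0.364 across batches. The groups are the 4 doses (1.7, 1.9, 2.1 and 2.3 Gy) by 4 days, with 6 animals each, 3 from each batch. The correlation of any 2 arrays ran from 0.720 to 0.987, so no array is a copy of another.

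Per the file headers, the scanner files were extracted with Agilent Feature Extraction 11.5.1.1, and their processed signal is an intensity, background-subtracted and spatially detrended within the array and not normalized between arrays. The authors also deposited a table of normalized values, which is on a log2 scale with column medians from 3.55 to 4.25. Its normalization is not stated. The deposited table correlated, array by array, with the scanner values at 0.966 to 0.993, and the batch difference had an SD over probes of 0.04 in it against 1.15 in the scanner values. The main values here are the scanner intensities, and the deposited table was used as an alternative.

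Each array has 45220 spots, of which 1417 are controls and were left out, leaving 43803 spots of 43603 probes. A median of 21712 spots per array were well above background by the software's own mark (11516 to 35701), no spot was saturated, and spots the software marked as outliers were left out, so that some genes have fewer than 24 animals. Log2 intensity was scaled by subtracting the 75th percentile of the non-control spots of the array. Spots of the same probe were averaged. Features had to be well above background on at least 6 arrays with at most 24 missing values, and the brightest probe stood for a gene, which left 33039 features. For 57 of them an animal coefficient could not be estimated, and 2 were not tested at 2.3 Gy on day 7.

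Gene names were taken from a RefSeq table of the pig assembly Sscrofa11.1 through the transcript accessions on the array. They cover 6893 probes with 3160 symbols, and 2936 of the tested features. The other 36710 probes, among them 12008 with Ensembl transcript numbers and 11718 with contig numbers, stay unnamed and enter only the counts. Of 619 members of 21 fixed lists 282 could be named: p53 targets 11 of 35, B cell markers 7 of 27, T cell markers 19 of 29, NK and cytotoxic markers 12 of 24, neutrophil markers 9 of 26, granule and immature neutrophil genes 11 of 24, monocyte markers 17 of 26, dendritic cell markers 6 of 20, eosinophil, basophil and mast cell genes 7 of 18, erythroid genes 7 of 36, heme synthesis genes 3 of 13, platelet genes 15 of 28, cell cycle genes 11 of 45, DNA repair genes 10 of 32, interferon-stimulated genes 25 of 40, inflammatory cytokine and NF-kB genes 25 of 36, complement and acute-phase genes 20 of 28, MHC class II genes 10 of 12, apoptosis genes 14 of 27, ribosomal protein genes 34 of 76 and housekeeping genes 9 of 17. Named members of the p53, interferon, inflammatory and ribosomal lists that did not pass the filters were not tested. Aliases in the table brought CELA2A into the granule list (for ELANE), CD1.1 for CD1A, LOC100151816 for IFIT5 and GP91-PHOX for CYBB.

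Changes were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 and data.table, version 1.17.8), with each animal as a fixed block and an effect for each of the 12 combinations of dose and day, leaving 60 residual degrees of freedom. The comparisons were each day against the day before irradiation averaged over doses, each dose and day, successive days, and the slope of the change on dose. Before irradiation, the dose groups were compared by an F test with batch in the model, and the batches with dose in the model. The animals' block holds the batch, and also the slide for all but 1 animal, but each day lies at a fixed slide position. Adjusted p-values follow Benjamini and Hochberg over the features of a comparison, with a threshold of 0.05.

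Lists were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Missing values were filled with fitted values for the list tests only. The dose trend of a list is the slope of the animals' mean change on dose, tested with 100000 permutations of dose within batch and adjusted over 60 tests of list and day, without the heme synthesis list, which has too few members. The comparison of 2.3 with 1.7 Gy used the exact test of all swaps within batch, whose smallest p is 0.005.

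Genes are named by a fixed rule. For each day it takes the 6 largest increases and the 6 largest decreases among called genes that changed the same way in at least 20 animals and were well above background on at least 12 of 24 arrays of the brighter day. For each list it takes the 3 members with the largest change on any day, and lets called members be named in a count of 5 or fewer. It adds the 5 genes with the smallest p for the dose slope per day, and a few fixed genes, among them CDKN1A, MDM2, BAX, FAS and CD3E. Some of the genes it selects are not described here.

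The tests were tested on simulated data, made from the fitted animal levels and normal noise of each feature's own spread, with 100 changed features of each size. On day 1 averaged over doses, 13.0% of changes of 0.5 and 85.0% of changes of 1 on the log2 scale were recovered, with 4 false calls. At 1.7 Gy alone the shares were 0.0% and 16.0%, for a dose slope on day 3 of 2 per Gy 14.0% and of 4 per Gy 68.0%, and for day 3 against day 1 a change of 1 was recovered in 83.0%. All 5 changed lists were recovered by camera.

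The alternatives were quantile normalization, normexp background correction (offset 50) followed by quantile normalization, the deposited table, no filter on dim probes (39693 features), a filter of 48 arrays (19571), all probes kept (36239), animals without a block or as a random effect (consensus correlation 0.197), batch by day terms, array quality weights, each batch alone, only the arrays compared, a 2-fold minimum, the correlation between genes estimated per list, the rotation test fry (which tests a list against no change, not against the other genes), and each animal left out in turn. The plan named the mean spot signal for normexp, which the files lack, and the median spot and background signals took its place. Added after seeing the data were a common floor under the scaled values (at -0.19), leaving out 2 animals with a doubted array, weights estimated gene by gene, and the granule list without CELA2A. The split of features by level into 3 equal sets was also made afterwards. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6). Survival was not analysed here.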

Results

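Whole blood from 24 male Göttingen minipigs was profiled before and after total-body irradiation with a cobalt-60 source, to learn which blood cells and which genes respond and whether the response grows with dose. Groups of 6 animals were given 1.7 Gy, 1.9 Gy, 2.1 Gy and 2.3 Gy, doses placed around the anticipated median lethal dose. Each animal gave 4 samples, taken the day before irradiation and on days 1, 3 and 7 after it, so that every change is a change within an animal. The animals came in 2 batches, each with 3 animals per dose. Survival was not analysed here.

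All 96 arrays were used. Of 43803 spots that carry pig sequence, a median of 21712 per array were well above background, from 11516 to 35701 between arrays, with medians of 17147 in batch 1 and 27546 in batch 2. The bright end of the arrays also differed between days: the 75th percentile of the signal had a median of 93.1 before irradiation, 77.6 on day 1, 265 on day 3 and 155 on day 7. Changes were tested for 33039 features, of which 2936 carry a gene name, and the number of arrays limits the precision of each of them. Gene values are log2 changes ± standard error, with n = 24 animals unless another n is given, and a called gene has an adjusted p below 0.05 from limma over all features. List shifts are medians over the members relative to the median of all features, which was 0.08 on day 1, -0.18 on day 3 and -0.16 on day 7, and the batch means ± SD beside them are means over the members in 12 animals per batch. On days 3 and 7 that median turned to 0.10 and 0.06 with quantile normalization, 0.01 and 0.00 with normexp, and 0.05 and 0.01 in the deposited values. It was -0.50 and -0.32 in batch 1 alone and 0.03 and -0.06 in batch 2 alone. The median also rose with level: in the dimmest, middle and brightest of 3 equal sets it was -0.51, -0.19 and 0.21 on day 3. On day 7 it was -0.39, -0.18 and 0.17. A list of mostly bright genes would thus shift upward without differing from features of like level. Lists were not compared with such features, and the housekeeping list also shifted up on both days. Counts of called members are from the adjustment over all features. The count adjusted over the list alone is given where it differs. The blood cell and response lists, their tests and the rule for naming genes were chosen before the data were examined, and the common floor named beside some lists was added after seeing the data. All p-values rest on treating the animals as separate units.

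Before irradiation no feature was called between the 4 dose groups, whereas the batches differed widely. With limma the count between dose groups was 0 of 33039, with 3040 at an unadjusted p below 0.05. Other settings did call features: quantile normalization 44, background correction by normexp 6, the deposited values 94, the filter of 48 arrays 3, and 128 when 2 animals with a doubted array were left out, a choice made after seeing the data. Differences between dose groups before irradiation are thus not excluded. Between batches 19192 features differed, 4294 higher and 14898 lower in batch 2, a split that turned to 8003 higher and 6278 lower with quantile normalization and 7406 higher and 7020 lower with normexp. A constant batch difference falls out of every comparison within an animal, but a change that itself differs between batches does not.

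B cells were the blood population whose transcripts fell most by day 1. MS4A1, which encodes the surface protein CD20, fell by 3.21 ± 0.16 (9.23-fold, adjusted p = 8.8e-26) and did so in 24 of 24 animals, and CD79A, a signalling chain of the B cell receptor, fell by 3.02 ± 0.16. Of 7 B cell markers 6 fell (7 adjusted over the list alone) and the list shifted by -2.47 (camera adjusted p = 5.7e-22, and 3.9e-07 with an estimated correlation), with batch means of -1.83 ± 0.40 and -2.08 ± 0.33 and all 24 animals in the same direction. Genes of MHC class II antigen presentation, which B cells share with monocytes and dendritic cells, fell with them: 6 of 10 members, among them SLA-DOA at -0.99 ± 0.12, SLA-DOB at -0.92 ± 0.15 and SLA-DQA1 at -0.57 ± 0.11. Their list shifted by -0.47 (camera adjusted p = 2.8e-05, adjusted p = 0.0834 with an estimated correlation). Batch means were -0.43 ± 0.38 and -0.34 ± 0.20, with 23 of 24 animals lower.

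T cell transcripts fell less than those of B cells on day 1, and cytotoxic transcripts went the other way. LEF1, a transcription factor of naive T cells, fell by 1.12 ± 0.15, GATA3, a regulator of helper T cells, by 1.02 ± 0.18 and IL7R, the receptor for a survival cytokine, by 0.96 ± 0.12, while CD3E, a chain of the T cell receptor complex, stood at -0.28 ± 0.11 (adjusted p = 0.0797). Of 19 T cell markers 9 fell (10 adjusted over the list alone), with a list shift of -0.36 (camera adjusted p = 1.2e-05, and 0.0433 with an estimated correlation). Batch means were -0.26 ± 0.23 and -0.44 ± 0.33, with 22 of 24 animals lower. Of 12 NK and cytotoxic markers 6 rose (8 adjusted over the list alone) and 1 fell. CCL5, a chemokine stored in cytotoxic granules, rose by 1.02 ± 0.13 and GZMB, a killing protease, by 0.74 ± 0.14, whereas GZMK, a granzyme of memory T cells, fell by 0.83 ± 0.14. This list shifted by 0.40 (camera adjusted p = 0.00296, adjusted p = 0.140 with an estimated correlation). Batch means were 0.40 ± 0.40 and 0.38 ± 0.17, with 22 of 24 animals higher.

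Neutrophil transcripts rose on day 1, both those of mature cells and those of granules made in the marrow. S100A9, S100A12 and S100A8, calcium-binding proteins that fill the neutrophil cytoplasm, rose by 1.03 ± 0.22 (n = 17), 1.03 ± 0.19 (n = 19) and 1.02 ± 0.20 (n = 21). Of 9 neutrophil markers 7 rose (9 adjusted over the list alone), a list shift of 0.92 (camera adjusted p = 1.6e-08, and 0.0211 with an estimated correlation). Batch means were 0.67 ± 0.50 and 1.00 ± 0.57, with 22 of 24 animals higher. LTF, the iron-binding lactoferrin of secondary granules, rose by 1.37 ± 0.21 and LCN2, a lipocalin that scavenges iron carriers, by 0.69 ± 0.18 (n = 22), whereas ARG1, an arginine-degrading enzyme, stood at -0.30 ± 0.27 (n = 17, adjusted p = 0.511). Of 11 granule genes 8 rose, a list shift of 0.59 (camera adjusted p = 3.2e-05, and 0.0410 with an estimated correlation). Batch means were 0.59 ± 0.39 and 0.65 ± 0.48, with 21 of 24 animals higher.

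Some transcripts of other myeloid cells and of platelets also rose on day 1. LGALS3, a lectin of macrophages, rose by 0.92 ± 0.12 (n = 21) and CD163, the haemoglobin scavenger receptor, by 0.50 ± 0.16, while VSIG4, a complement receptor of tissue macrophages, was not called at 0.18 ± 0.28. Of 17 monocyte markers 6 rose, yet the list shift was only 0.10 (camera adjusted p = 0.0110, adjusted p = 0.181 with an estimated correlation; 19 of 24 animals higher), and batch 1 alone did not call it (batch means 0.14 ± 0.24 and 0.38 ± 0.40, camera adjusted p = 0.518 in batch 1). ALOX15, a lipoxygenase of eosinophils, rose by 1.27 ± 0.20 and KIT, the stem cell factor receptor of mast cells, by 0.60 ± 0.11, while IL13, a cytokine of type 2 immunity, was not called at -0.07 ± 0.21. Of 7 eosinophil, basophil and mast cell genes 4 rose, a list shift of 0.51 (camera adjusted p = 0.00384, and 0.0211 with an estimated correlation). Batch means were 0.53 ± 0.28 and 0.43 ± 0.29, with 22 of 24 animals higher. GP1BB, a chain of the platelet receptor for von Willebrand factor, rose by 0.88 ± 0.22, and 10 of 15 platelet genes rose, though SPARC at 0.70 ± 0.39 and VWF at 0.59 ± 0.28 were not called, a list shift of 0.67 (camera adjusted p = 1.2e-05, adjusted p = 0.0613 with an estimated correlation). Batch means were 0.54 ± 0.35 and 0.77 ± 0.45, with 21 of 24 animals higher. Among 6 dendritic cell markers XCR1, a chemokine receptor, rose by 0.75 ± 0.16, TLR3, a sensor of viral RNA, and 2 others fell, and TLR9 was not called at -0.06, nor was the list at -0.33 (camera adjusted p = 0.211), though it was called down with all probes kept (0.0134). Of 7 erythroid genes only RHCE, a blood group antigen, fell, by 0.86 ± 0.26 (n = 22), and neither TRIM10 at -0.59, HBE1 at -0.19 (n = 21) nor the list at -0.27 was called (camera adjusted p = 0.216). Of 3 heme synthesis genes TSPO rose, UROS was not called at -0.09, and the list was not called at -0.17 (camera adjusted p = 0.817).

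Several known p53 targets rose on day 1. MDM2, the ubiquitin ligase that restrains p53, rose by 1.31 ± 0.19 (2.49-fold, adjusted p = 9.1e-08, 23 of 24 animals), CCNG1, a cyclin induced by p53, by 1.45 ± 0.14 (n = 17, 17 of 17 animals) and FAS, a death receptor, by 0.78 ± 0.12. GDF15, a stress cytokine, was well above background on 0 of 24 arrays before irradiation and on 10 of 24 on day 1, so no fold is given for it. Of 10 p53 targets 4 rose, and adjusted over the list alone 4 rose and 1 fell. Their list shifted by 0.25 (camera adjusted p = 0.00830, adjusted p = 0.0613 with an estimated correlation; 19 of 24 animals higher), or by 0.02 with GDF15 held at its bound, and batch 1 alone did not call it (batch means 0.16 ± 0.48 and 0.66 ± 0.48, camera adjusted p = 0.196 in batch 1). CDKN1A and BAX have no named probe.

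Genes of DNA repair fell on day 1, 2 mitotic cyclins fell, and genes of cell death were mixed. ATM, the kinase that senses double-strand breaks, fell by 0.61 ± 0.17 (n = 23, with other probes of the opposite direction). Of 10 DNA repair genes 5 fell (6 adjusted over the list alone), a list shift of -0.37 (camera adjusted p = 0.000966, and 0.0433 with an estimated correlation). Batch means were -0.21 ± 0.12 and -0.43 ± 0.21, with 23 of 24 animals lower. Of 11 cell cycle genes only CCNB1 and CCNB2, the cyclins that drive entry into mitosis, fell (3 adjusted over the list alone), and TOP2A at -0.57, AURKB at -0.15 and PBK at -0.11 were not called, a list shift of -0.27 (camera adjusted p = 0.0188, adjusted p = 0.157 with an estimated correlation; 19 of 24 animals lower). That call was lost with normexp (0.0505), with the filter of 48 arrays (0.0894), with the common floor (0.493) and in batch 1 alone (0.208; batch means -0.11 ± 0.36 and -0.39 ± 0.23). BCL2A1, a survival factor of the BCL2 family, rose by 0.65 ± 0.15, while BCL2L1, another of that family, was not called at -0.24 ± 0.19. Of 14 apoptosis genes 5 rose and 1 fell (5 and 2 adjusted over the list alone), and the list was not called at 0.15 (camera adjusted p = 0.322).

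Innate immune genes split on day 1, with interferon-stimulated genes down and inflammatory and complement genes up. OASL, an antiviral sensor, fell by 1.34 ± 0.21, CXCL10, a chemokine for T cells, by 1.13 ± 0.30 and RSAD2, an antiviral enzyme, by 0.98 ± 0.25. Of 23 interferon-stimulated genes 9 fell (11 adjusted over the list alone), a list shift of -0.43 (camera adjusted p = 0.000419, adjusted p = 0.293 with an estimated correlation; 20 of 24 animals lower), and batch 2 alone did not call it (batch means -0.57 ± 0.39 and -0.24 ± 0.97, camera adjusted p = 0.223 in batch 2). ICAM1, an adhesion molecule, rose by 1.07 ± 0.15 and CCL3L1, a chemokine for monocytes, by 0.94 ± 0.13, while LIF, a cytokine of the interleukin-6 family, stood at 0.13 (adjusted p = 0.735). Of 24 inflammatory genes 8 rose (11 adjusted over the list alone), a list shift of 0.28 (camera adjusted p = 0.000135, and 0.0433 with an estimated correlation). Batch means were 0.25 ± 0.29 and 0.54 ± 0.39, with 21 of 24 animals higher. C1QB, a chain of the complement component C1q, rose by 1.59 ± 0.35 (well above background on 5 of 24 arrays before and 17 of 24 on day 1; not called with normexp), while C3, the central complement protein, stood at 0.03 and CRP, the C-reactive protein, at 0.20, neither called. Of 20 complement and acute-phase genes 8 rose, a list shift of 0.27 (camera adjusted p = 4.1e-05, and 0.0433 with an estimated correlation). Batch means were 0.53 ± 0.46 and 0.53 ± 0.44, with 22 of 24 animals higher.

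Ribosomal protein genes fell on day 1 and housekeeping genes were not called as a list. RPL5, a protein of the large subunit, fell by 0.79 ± 0.10 (n = 20) and RPL23, another of them, by 0.63 ± 0.16 (n = 12), while RPLP0 was not called at -0.13 (n = 23). Of 33 ribosomal genes 28 fell, a list shift of -0.47 (camera adjusted p = 1.8e-24, and 0.0410 with an estimated correlation). Batch means were -0.39 ± 0.27 and -0.42 ± 0.37, with 23 of 24 animals lower. Among 9 housekeeping genes HPRT1, an enzyme of purine salvage, rose by 0.72 ± 0.13 (n = 19), PGK1, an enzyme of glycolysis, by 0.38 ± 0.11 (n = 22), and GUSB, a lysosomal enzyme, fell by 0.45 ± 0.11 (n = 21). In all 2 rose and 3 fell, and the list stood at 0.05 (camera adjusted p = 0.817).

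Among the genes that the naming rule selects outside the lists, LY6G6D had the largest increase of day 1 and ID3 the largest decrease. LY6G6D, a surface protein of the Ly6 family, rose by 2.13 ± 0.19 (4.37-fold, 24 of 24 animals), LGALS13, a galectin, by 1.87 ± 0.19, RETN, the inflammatory peptide resistin, by 1.78 ± 0.17, CD70, a ligand that activated lymphocytes display, by 1.74 ± 0.14, and GJA4, a gap junction protein of arteries, by 1.56 ± 0.20. CD72, a B cell coreceptor, fell by 2.39 ± 0.11, ID3, an inhibitor of transcription factors in lymphocytes, fell by 2.40 ± 0.18 (n = 20) and ANGPTL4, a lipase inhibitor, by 2.37 ± 0.19.

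On day 1 limma called 6375 features against the sample taken before irradiation, 3225 up and 3150 down, of which 373 rose and 234 fell at least 2-fold. Of 21 lists 16 were called, 9 up and 7 down, and 9 of them also with an estimated correlation. In batch 1 alone only 1976 features were called, against 6356 in batch 2 alone. Every day 1 array lay at a different slide position from the array it is compared with.

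**Figure D1:**
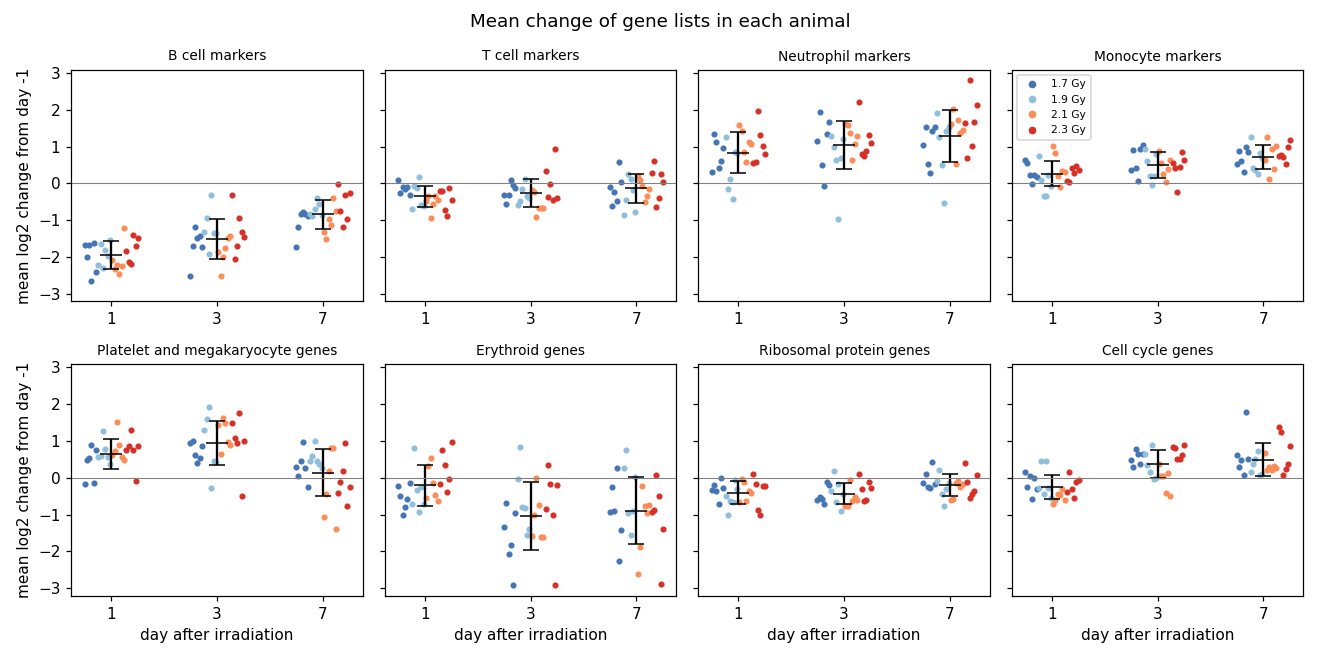
Mean log2 change of the members of 8 gene lists against the sample before irradiation (vertical axis) on days 1, 3 and 7 (horizontal axis), in whole blood of 24 minipigs. Each point is an animal coloured by its dose, and the bars give the mean and SD over the animals.

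B cell transcripts were still far below their starting level on day 3. MS4A1 was down by 2.46 ± 0.16 and CD79A by 1.87 ± 0.16, 6 of 7 markers fell, and the list stood at -1.70 (camera adjusted p = 5.3e-05, adjusted p = 0.0707 with an estimated correlation). Batch means were -1.38 ± 0.44 and -1.64 ± 0.62, with all 24 animals lower. Among 19 T cell markers 9 fell and 2 rose. LEF1 fell by 0.90 ± 0.15, GATA3 by 0.78 ± 0.18 and IL7R by 0.60 ± 0.13 (n = 23), CD4 and LCK rose, and CD3E stood at -0.12 ± 0.11 (adjusted p = 0.390). The T cell list was not called at -0.11 (camera adjusted p = 0.306), but was called down at -0.44 with quantile normalization (0.00862), at -0.36 with normexp (0.00465) and at -0.40 in the deposited values (0.00818), and also with the common floor (0.00227) and all probes kept (0.0444). Of 12 NK and cytotoxic markers 6 rose and 1 fell, with CCL5 at 0.78 ± 0.13 and GZMB at 0.65 ± 0.14, while the call of GZMK at 0.34 ± 0.14 (n = 22) was lost under all 3 other scalings. That list stood at 0.55 (camera adjusted p = 0.0204, adjusted p = 0.238 with an estimated correlation; 19 of 24 animals higher), a call lost with quantile normalization (0.203), normexp (0.214), the deposited values (0.226) and the filter of 48 arrays (0.230) and in batch 2 alone (0.288; batch means 0.39 ± 0.63 and 0.27 ± 0.32).

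Monocyte and neutrophil transcripts rose on day 3. CD163 rose by 1.65 ± 0.16 (n = 23) and LGALS3 by 1.40 ± 0.13 (n = 19). Of 17 monocyte markers 13 rose and 3 fell, a list shift of 0.94 (camera adjusted p = 4.0e-05, adjusted p = 0.0707 with an estimated correlation). Batch means were 0.56 ± 0.34 and 0.43 ± 0.35, with 22 of 24 animals higher. The falls were of FCN2, SIGLEC1 and VSIG4. VSIG4 fell by 1.83 ± 0.28 in its brightest probe and stood at 1.53 in another, and FCN2 was well above background on no array before irradiation. All 9 neutrophil markers rose, with S100A12 at 0.76 ± 0.19 (n = 19), S100A8 at 0.71 ± 0.20 (n = 21) and S100A9 at 0.70 ± 0.21 (n = 19), a list shift of 1.1 (camera adjusted p = 2.0e-06, adjusted p = 0.0707 with an estimated correlation). Batch means were 0.91 ± 0.67 and 1.17 ± 0.63, with 22 of 24 animals higher. Among 11 granule genes 6 rose and 2 fell, with ARG1 down by 1.70 ± 0.27 (n = 17), while LTF at 0.24 ± 0.21 (adjusted p = 0.338) and LCN2 at 0.06 ± 0.18 (n = 22) were not called. Their list stood at 0.98 (camera adjusted p = 0.0112, adjusted p = 0.207 with an estimated correlation; 19 of 24 animals higher), and batch 2 alone did not call it (batch means 0.29 ± 0.48 and 0.55 ± 0.76, camera adjusted p = 0.0530 in batch 2). The call was also lost with the filter of 48 arrays (0.122) and with the common floor, where the shift was 0.05 (0.102).

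Platelet transcripts were raised on day 3 and red cell transcripts fell. SPARC, a matrix glycoprotein stored in platelet granules, rose by 2.73 ± 0.39 in 22 of 24 animals, well above background on 8 of 24 arrays before and 22 of 24 on day 3, though its probes ran from -0.35 to 2.73. VWF, the adhesive protein of platelets and vessel lining, rose by 2.27 ± 0.28 (another probe at -0.12) and GP1BB by 1.70 ± 0.22. Of 15 platelet genes 12 rose and 2 fell, a list shift of 1.46 (camera adjusted p = 5.3e-05, adjusted p = 0.144 with an estimated correlation). Batch means were 0.73 ± 0.63 and 1.16 ± 0.51, with 22 of 24 animals higher. RHCE fell by 2.14 ± 0.26 (n = 22), TRIM10, a protein of terminal red cell maturation, by 1.46 ± 0.24 (15 of 24 arrays before and 17 of 24 then) and HBE1, a globin chain, by 1.23 ± 0.22 (n = 23). Of 7 erythroid genes 5 fell, a list shift of -1.05 (camera adjusted p = 0.0204, adjusted p = 0.238 with an estimated correlation; batch means -1.17 ± 1.17 and -0.90 ± 0.61, 22 of 24 animals lower), a call lost when dim probes were kept (0.0571). UROS, an enzyme of heme synthesis, fell by 0.99 ± 0.20 (n = 16), while TSPO, a mitochondrial carrier, rose by 0.93 ± 0.11 (n = 18), and their list of 3 was not called at -0.81 (camera adjusted p = 0.610).

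Lists of eosinophil, basophil and mast cell genes and of cell cycle genes were called up on day 3, and both calls depended on the processing. KIT rose by 1.30 ± 0.11 and ALOX15 by 0.96 ± 0.20, while IL13 fell by 1.44 ± 0.21 (well above background on 10 of 24 arrays before and 11 of 24 then). Of 7 eosinophil, basophil and mast cell genes 5 rose and 2 fell, a list shift of 0.93 (camera adjusted p = 0.0235, adjusted p = 0.0707 with an estimated correlation). Batch means were 0.34 ± 0.36 and 0.43 ± 0.40, with 21 of 24 animals higher. The call was lost with quantile normalization (0.180), normexp (0.126) and the deposited values (0.192) and in batch 2 alone (0.171). PBK, a mitotic kinase, rose by 1.13 ± 0.17 (another probe at -0.23) and TOP2A, the topoisomerase of dividing cells, by 1.06 ± 0.22, while AURKB, a kinase of chromosome segregation, fell by 1.32 ± 0.20 in its brightest probe and stood at 0.92 in another. Of 11 cell cycle genes 7 rose and 2 fell, a list shift of 0.70 (camera adjusted p = 0.0235, adjusted p = 0.207 with an estimated correlation; 21 of 24 animals higher). Quantile normalization (0.203), normexp (0.183) the deposited values (0.185), the filter of 48 arrays (0.239) and the common floor (0.939) lost the call, as did batch 2 alone (0.164; batch means 0.38 ± 0.49 and 0.38 ± 0.27). Dendritic cell markers (XCR1 up by 1.1 ± 0.16, another probe at -0.36; TLR9 up by 0.42 ± 0.17; TLR3 not called at 0.20; 2 of 6 rose, 1 adjusted over the list alone) were not called as a list at 0.34 (camera adjusted p = 0.147), though batch 1 alone called them up (0.0314).

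Complement and inflammatory genes went both ways on day 3. C1QB rose by 2.08 ± 0.35, while C3 fell by 2.23 ± 0.24 in its brightest probe (1.21 in another) and CRP fell by 2.03 ± 0.27. Of 20 complement and acute-phase genes 11 rose and 6 fell, a list shift of 0.69 (camera adjusted p = 0.00702, adjusted p = 0.207 with an estimated correlation). Batch means were 0.08 ± 0.51 and 0.52 ± 0.62, with 15 of 24 animals higher. CCL3L1 rose by 1.56 ± 0.13 in 24 of 24 animals and ICAM1 by 1.46 ± 0.16 (n = 23), whereas LIF fell by 1.70 ± 0.20 (well above background on 9 of 24 arrays before and 10 of 24 then). Of 24 inflammatory genes 11 rose (12 adjusted over the list alone) and 4 fell, a list shift of 0.55 (camera adjusted p = 0.00702, adjusted p = 0.203 with an estimated correlation; 18 of 24 animals higher), or 0.54 with CCL2 and CXCL2 held at their bounds. Quantile normalization (0.0561) and the deposited values (0.0750) lost the call, as did batch 2 alone (0.0694; batch means 0.10 ± 0.31 and 0.37 ± 0.36). Among 23 interferon-stimulated genes 7 fell and 4 rose, with RSAD2 down by 1.24 ± 0.26 (n = 22) and CXCL10 down by 1.14 ± 0.30, while OASL was not called at -0.32. Their list was not called at -0.04 (camera adjusted p = 0.900) but was called down at -0.33 with quantile normalization (0.0310), at -0.32 with normexp (0.0163) at -0.36 in the deposited values (0.0454) and at -0.22 with the common floor (0.0239).

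Several p53 targets stayed up on day 3, and lists of cell death and housekeeping genes were called up. MDM2 was up by 1.12 ± 0.19, FAS by 0.94 ± 0.12 and CCNG1 by 0.63 ± 0.14 (n = 17; the deposited values lost its call), yet with 4 of 10 up and 2 down the list was not called at 0.49 (camera adjusted p = 0.108), though batch 1 alone called it up (0.0254). BCL2A1 rose by 0.85 ± 0.17 (n = 19), while BCL2L1 fell by 1.04 ± 0.19. Of 14 apoptosis genes 7 rose and 1 fell, a list shift of 0.46 (camera adjusted p = 0.00702, adjusted p = 0.203 with an estimated correlation; 18 of 24 animals higher). That call was lost with quantile normalization (0.180), normexp (0.166), the deposited values (0.226) and the filter of 48 arrays (0.122) and in batch 2 alone (0.312; batch means 0.31 ± 0.31 and 0.22 ± 0.33). HPRT1 rose by 1.51 ± 0.14 (n = 15) and PGK1 by 0.89 ± 0.11 (n = 22) and GUSB by 0.48 ± 0.12 (n = 20), and 5 of 9 housekeeping genes rose, a list shift of 0.52 (camera adjusted p = 0.00122, adjusted p = 0.0707 with an estimated correlation). Batch means were 0.40 ± 0.24 and 0.37 ± 0.23, with 23 of 24 animals higher. ATM was not called at -0.22, and the DNA repair list (3 of 10 up, 1 adjusted over the list alone, and 2 down) was not called at 0.29 (camera adjusted p = 0.607).

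Translation and antigen presentation stayed low or mixed on day 3. RPL5 was down by 0.37 ± 0.10 (n = 19) and RPL23 by 0.73 ± 0.17 (n = 11). RPLP0, a protein of the ribosomal stalk, was called at -0.71 ± 0.10 (n = 23), but its value shrank to -0.11 with quantile normalization and it lost the call under all 3 other scalings. Of 33 ribosomal genes 30 fell (31 adjusted over the list alone), a list shift of -0.26 (camera adjusted p = 2.0e-06, adjusted p = 0.244 with an estimated correlation; 22 of 24 animals lower). Batch 1 alone did not call it and turned the shift to 0.17 (batch means -0.32 ± 0.25 and -0.54 ± 0.30, camera adjusted p = 0.171 in batch 1). Among 10 MHC class II genes SLA-DOB fell by 1.24 ± 0.15 and SLA-DOA by 0.27 ± 0.12, SLA-DQA1 was not called at 0.16, SLA-DMA, SLA-DMB and SLA-DRB1 rose, and the list with 3 up (4 adjusted over the list alone) and 3 down was not called at 0.36 (camera adjusted p = 0.306), though batch 1 alone called it up (0.0374).

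Of the rule's genes outside the lists, CD70 had the largest increase of day 3 and CD163L1 the largest decrease. CD70 rose by 2.29 ± 0.14 in 24 of 24 animals, GJA4 by 2.20 ± 0.20 and MMP2, a matrix-degrading enzyme, by 2.05 ± 0.34 (well above background on 6 of 24 arrays before and 18 of 24 then). CD163L1, a scavenger receptor of T cells and macrophages, fell by 2.69 ± 0.17 in 24 of 24 animals, SNCG, a synuclein, by 2.60 ± 0.25 (n = 22) and PROC, the anticoagulant protein C, by 2.60 ± 0.23. IHH, a hedgehog ligand, fell by 2.65 ± 0.26 (another probe at -1.14), CAV3, a caveolin of muscle, by 2.59 ± 0.25 and SPEF2, a protein of sperm tails, by 2.52 ± 0.26 (another probe at -0.98). On this day ATM, SLA-DQA1 and TLR3 also had a dimmer probe of opposite sign. With normexp the falls were smaller, at -0.77 for CD163L1, -0.55 for PROC and -1.09 for IHH.

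On day 3 limma called 18768 features, 6831 up and 11937 down (36.4% up), of which 1497 rose and 4754 fell at least 2-fold. Other scalings turned the split, to 9852 up and 6979 down with quantile normalization (58.5% up), 8691 and 7321 with normexp (54.3%) and 9176 and 8181 in the deposited values (52.9%), and the batches differed, with 5129 up and 15786 down in batch 1 alone against 8618 and 7931 in batch 2 alone. Of 21 lists 14 were called, 11 up and 3 down, and none of the 14 with an estimated correlation. The excess of decreases lay in dim features: of the dimmest set 5709 fell and 151 rose, of the middle set 4286 fell and 1965 rose, and of the brightest set 1942 fell and 4715 rose.

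**Figure D2:**
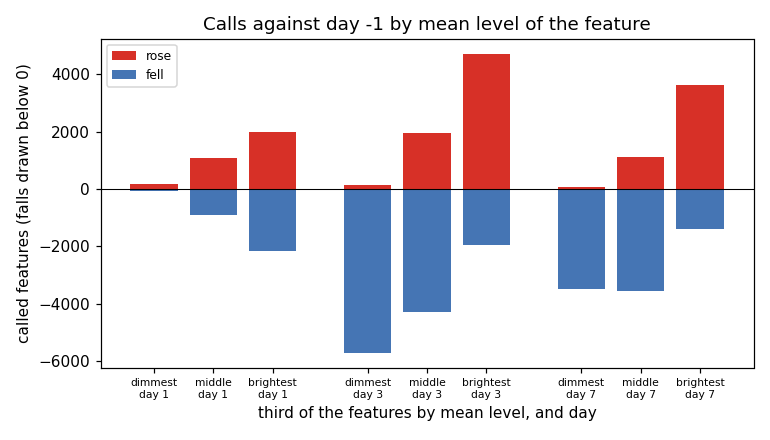
Number of features called up and down against the sample before irradiation (vertical axis) on days 1, 3 and 7, for 3 sets of 11013 features ordered by mean level (horizontal axis). Each bar is a count from limma at an adjusted p below 0.05, n = 24 animals.

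Monocyte and neutrophil transcripts rose most clearly of all lists on day 7. CD163 was up by 1.96 ± 0.16 in 23 of 24 animals and LGALS3 by 1.21 ± 0.12 (n = 21), while VSIG4 was down by 1.00 ± 0.28 in its brightest probe. Of 17 monocyte markers 14 rose and 1 fell, a list shift of 1.1 (camera adjusted p = 1.3e-11, and 0.00148 with an estimated correlation). Batch means were 0.76 ± 0.29 and 0.68 ± 0.35, with all 24 animals higher. S100A9, S100A12 and S100A8 rose by 1.87 ± 0.20 (n = 21), 1.86 ± 0.18 (n = 21) and 1.77 ± 0.20 (n = 22), and all 9 neutrophil markers rose, a list shift of 1.24 (camera adjusted p = 1.2e-13, and 0.00148 with an estimated correlation). Batch means were 1.23 ± 0.70 and 1.36 ± 0.73, with 23 of 24 animals higher. These were the only list calls of day 7 that held with an estimated correlation. Of 11 granule genes 5 rose and 2 fell, with LTF up by 1.95 ± 0.22 (n = 22), LCN2 up by 1.38 ± 0.18 (n = 23) and ARG1 down by 1.21 ± 0.27 (n = 17), a list shift of 0.54 (camera adjusted p = 0.00237, adjusted p = 0.106 with an estimated correlation). Batch means were 0.33 ± 0.55 and 0.49 ± 0.55, with 17 of 24 animals higher.

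B cell transcripts had partly returned by day 7, and T cell markers still included genes below their start. MS4A1 was down by 1.47 ± 0.16 in 24 of 24 animals and CD79A by 1.23 ± 0.16. Of 7 B cell markers 5 fell and CD180, a receptor that tunes B cell activation, rose by 0.52 ± 0.15, a list shift of -1.02 (camera adjusted p = 0.000934, adjusted p = 0.0625 with an estimated correlation). Batch means were -0.75 ± 0.26 and -0.92 ± 0.49, with all 24 animals lower. Among T cell markers GATA3 was down by 0.88 ± 0.18 (n = 23), IL7R by 0.37 ± 0.12 and LEF1 by 0.36 ± 0.15, 7 of 19 fell and 2 rose, and CD3E stood at -0.08 (adjusted p = 0.583). The T cell list was not called at -0.02 (camera adjusted p = 0.510), though it was called down at -0.24 with quantile normalization (0.0191), at -0.19 with normexp (0.0222) and at -0.26 in the deposited values (0.0133), and also with the common floor (0.00346). Of 12 NK and cytotoxic markers 2 rose (1 adjusted over the list alone) and 1 fell (0 adjusted over the list alone), GZMB stood at 0.14 and CCL5 at 0.29, neither called, GZMK lost its call with quantile normalization, and the list was not called at 0.29 (camera adjusted p = 0.207), though batch 1 alone called it up (0.0498). Dendritic cell markers rose, with XCR1 at 0.78 ± 0.16, TLR9, a sensor of bacterial DNA, at 0.62 ± 0.17 (n = 23) and 4 of 6 up, and TLR3 not called at 0.19. Their list shifted by 0.60 (camera adjusted p = 0.00681, adjusted p = 0.0625 with an estimated correlation; batch means 0.50 ± 0.37 and 0.35 ± 0.32, 23 of 24 animals higher), a call lost with normexp (0.0864), the deposited values (0.0766), the filter of 48 arrays (0.0929) and all probes kept (0.0588).

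Red cell transcripts remained low on day 7 and platelet transcripts had come down. HBE1 was down by 1.40 ± 0.22 (n = 23), RHCE by 1.22 ± 0.28 (n = 19) and TRIM10 by 1.20 ± 0.24. Of 7 erythroid genes 5 fell, a list shift of -0.94 (camera adjusted p = 0.00237, adjusted p = 0.132 with an estimated correlation). Batch means were -1.08 ± 0.96 and -0.72 ± 0.87, with 19 of 24 animals lower. In the heme synthesis list TSPO rose by 0.58 ± 0.12 (n = 14), UROS fell by 0.49 ± 0.19 (n = 19), and the list was not called at -0.30 (camera adjusted p = 0.798). SPARC was still up by 1.87 ± 0.39 (well above background on 20 of 24 arrays) and VWF by 1.25 ± 0.28, with another VWF probe at -0.37, and GP1BB at 0.57 ± 0.22 lost its call under all 3 other scalings. With 3 of 15 platelet genes up and 3 down, their list was not called at 0.19 (camera adjusted p = 0.511). KIT was up by 0.95 ± 0.11, whereas ALOX15 fell by 0.87 ± 0.20 and IL13 by 0.74 ± 0.21 (lost with quantile normalization; 11 of 24 arrays), and with 2 of 7 up and 4 down the eosinophil, basophil and mast cell list was not called at -0.56 (camera adjusted p = 0.910).

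Lists of cell cycle and apoptosis genes were called up on day 7, though not with an estimated correlation. PBK was up by 1.46 ± 0.17, TOP2A by 1.36 ± 0.22, and AURKB down by 0.99 ± 0.20 in its brightest probe. Of 11 cell cycle genes 7 rose and 1 fell, a list shift of 0.74 (camera adjusted p = 0.000502, adjusted p = 0.0625 with an estimated correlation). Batch means were 0.61 ± 0.49 and 0.39 ± 0.38, with all 24 animals higher. BCL2A1 was up by 0.94 ± 0.16 (n = 21), and BCL2L1 was down by 0.70 ± 0.19. Of 14 apoptosis genes 8 rose (9 adjusted over the list alone) and 1 fell, a list shift of 0.51 (camera adjusted p = 0.000215, adjusted p = 0.0625 with an estimated correlation). Batch means were 0.32 ± 0.28 and 0.29 ± 0.26, with 21 of 24 animals higher. MDM2 remained up by 0.73 ± 0.19 and FAS by 0.67 ± 0.12, while CCNG1 at 0.41 ± 0.13 (n = 20) lost its call under all 3 other scalings, and with 3 of 10 up and 1 down the p53 list was not called at 0.43 (camera adjusted p = 0.0618). It was called up with batch by day terms in the animal block (0.0424), without the block and so without the pairing (0.0404), with no filter on dim probes (0.0460) and in batch 1 alone (0.0269). ATM was not called at 0.04, and the DNA repair list with 2 of 10 up and 2 down was not called at 0.18 (camera adjusted p = 0.552).

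Complement and inflammatory genes were raised on day 7, and interferon-stimulated genes less clearly. C1QB was up by 2.25 ± 0.35 in 23 of 24 animals, while C3 at -1.20 ± 0.24 and CRP at -1.14 ± 0.27 (n = 23) were down. Of 20 complement and acute-phase genes 10 rose and 3 fell, a list shift of 0.56 (camera adjusted p = 0.000215, adjusted p = 0.0625 with an estimated correlation). Batch means were 0.42 ± 0.63 and 0.51 ± 0.41, with 21 of 24 animals higher. ICAM1 was up by 1.14 ± 0.15 and CCL3L1 by 0.86 ± 0.13, and LIF down by 0.92 ± 0.20 (11 of 24 arrays). Of 24 inflammatory genes 12 rose and 3 fell, a list shift of 0.42 (camera adjusted p = 0.000502, adjusted p = 0.0625 with an estimated correlation). Batch means were 0.17 ± 0.38 and 0.37 ± 0.40, with 18 of 24 animals higher. Of 23 interferon-stimulated genes 6 rose and none fell, while OASL, RSAD2 and CXCL10 were not called at -0.47, -0.36 and 0.30. Their list shifted by 0.39 (camera adjusted p = 0.00758, adjusted p = 0.581 with an estimated correlation; batch means 0.15 ± 0.40 and 0.24 ± 0.61, 14 of 24 animals higher), and quantile normalization (0.491), normexp (0.813), the deposited values (0.459), the filter of 48 arrays (0.237) and the common floor (0.0764) lost the call.

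Some antigen presentation and translation genes were still down on day 7, and housekeeping genes were up. SLA-DOB was down by 1.08 ± 0.15 and SLA-DOA by 0.42 ± 0.12, SLA-DQA1 was not called at 0.12, and with 2 of 10 up (3 adjusted over the list alone) and 3 down the MHC class II list was not called at 0.28 (camera adjusted p = 0.451). Of 33 ribosomal genes 13 fell (15 adjusted over the list alone), a list shift of -0.06 (camera adjusted p = 0.00237, adjusted p = 0.596 with an estimated correlation; 19 of 24 animals lower), and the call was lost with quantile normalization (0.0699), normexp (0.286) and the deposited values (0.455) and in batch 1 alone (0.498; batch means -0.13 ± 0.30 and -0.25 ± 0.30), where the shift turned to 0.16. RPLP0 was called at -0.30 ± 0.10, but turned positive under all 3 other scalings, to 0.11 with quantile normalization. RPL5 stood at -0.19 (adjusted p = 0.101), and the call of RPL23 at -0.46 ± 0.17 (n = 11) was lost with quantile normalization. PGK1 was up by 0.69 ± 0.11 (n = 23), HPRT1 at 0.39 ± 0.12 (n = 21) lost its call under all 3 other scalings and GUSB at 0.35 ± 0.11 (n = 22) with quantile normalization. With 5 of 9 up the housekeeping list shifted by 0.48 (camera adjusted p = 0.00297, adjusted p = 0.0705 with an estimated correlation), a call lost with the filter of 48 arrays (0.0712). Batch means were 0.28 ± 0.19 and 0.27 ± 0.26, with 22 of 24 animals higher.

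The largest changes of day 7 included MIOX, an enzyme of inositol breakdown, up by 2.46 ± 0.32 (5.51-fold, 21 of 24 animals), CD70, up by 2.11 ± 0.14, and MUC19, a gel-forming mucin, up by 1.98 ± 0.16 (n = 22). CD163L1 was down by 2.55 ± 0.17, FAM110B, a centrosomal protein, by 1.96 ± 0.21, FXYD3, a regulator of the sodium pump, by 1.96 ± 0.25 and ID3 by 1.81 ± 0.18 (n = 20). TMEM86B, an enzyme of ether lipid breakdown, was down by 1.72 ± 0.23 and SLC30A3, a zinc transporter, by 1.60 ± 0.20. For ATM, AURKB, C3, PBK, RPL5, SLA-DQA1, SPARC, TLR3, VSIG4, VWF and XCR1 the brightest probe, which gives the value, had a dimmer probe of opposite sign on this day.

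On day 7 limma called 13254 features, 4801 up and 8453 down (36.2% up), of which 514 rose and 680 fell at least 2-fold. Other scalings turned or levelled the split, to 5861 up and 4683 down with quantile normalization (55.6% up), 5255 and 5067 with normexp (50.9%) and 5292 and 5523 in the deposited values (48.9%). Of the dimmest set 3474 features fell and 64 rose, of the brightest set 1403 fell and 3622 rose. Of 21 lists 13 were called, 10 up and 3 down, and 2 of them with an estimated correlation.

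Between the sampling days, B cell transcripts recovered while platelet and eosinophil transcripts came down. From day 3 to day 7 all 7 B cell markers rose, a list shift of 0.58 (camera adjusted p = 7.5e-06, and 0.0152 with an estimated correlation). Of 15 platelet genes 10 fell (12 adjusted over the list alone) and 2 rose, a shift of -1.09 (camera adjusted p = 4.8e-11, and 0.0152 with an estimated correlation). Of 7 eosinophil, basophil and mast cell genes 4 fell and 1 rose, a shift of -0.42 (camera adjusted p = 6.3e-05, and 0.000787 with an estimated correlation). Ribosomal genes rose by 0.17 (13 of 33, 21 adjusted over the list alone; camera adjusted p = 7.8e-08, adjusted p = 0.515 with an estimated correlation) and interferon-stimulated genes by 0.36 (8 of 23, 10 adjusted over the list alone; camera adjusted p = 0.000373, adjusted p = 0.616 with an estimated correlation). From day 1 to day 3 cell cycle genes rose by 1.26 (7 of 11 up, 2 down; camera adjusted p = 0.00116, adjusted p = 0.147 with an estimated correlation), MHC class II genes by 0.76 (8 of 10 up, 1 down, or 2 down adjusted over the list alone; camera adjusted p = 0.000922, adjusted p = 0.242 with an estimated correlation) and B cell markers by 0.78 (6 of 7 up, 1 down; camera adjusted p = 0.00534, adjusted p = 0.184 with an estimated correlation).

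Between days 1 and 3 limma called 19006 features, 6708 up and 12298 down (35.3% up), against 9044 and 6104 with quantile normalization (59.7%), 8046 and 6333 with normexp (56.0%) and 7678 and 6371 in the deposited values (54.7%). Between days 3 and 7 it called 4936, 2895 up and 2041 down (58.7% up), against 1837 and 2665 with normexp (40.8%).

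B cell markers, receptors and signalling proteins of antibody-producing cells, fell at each dose on day 1. Their mean change on day 1 was -2.01 ± 0.44 (SD, n = 6) at 1.7 Gy, -1.92 ± 0.30 at 1.9 Gy, -2.09 ± 0.45 at 2.1 Gy and -1.80 ± 0.33 at 2.3 Gy, with all 6 animals lower at every dose. In groups of 6 animals limma called 103 features up and 99 down on day 1 at 1.7 Gy, 162 and 386 at 1.9 Gy, 944 and 826 at 2.1 Gy, and 886 and 816 at 2.3 Gy. On day 3 it called 3268 up and 7972 down at 1.7 Gy, 1201 and 600 at 1.9 Gy, 3285 and 4923 at 2.1 Gy, and 4073 and 4633 at 2.3 Gy. On day 7 it called 653 and 810, 533 and 112, 1138 and 1615, and 2507 and 5351 in the same order of dose. Without 2 animals that have a doubted array, a choice made after seeing the data, the 1.9 Gy group had 5527 calls on day 3, 1482 up and 4045 down, and the 1.7 Gy group 3258 on day 7. Leaving out single animals also moved these counts. On day 1 they ran between 109 and 239 at 1.7 Gy, 239 and 684 at 1.9 Gy, 978 and 1975 at 2.1 Gy, and 724 and 1980 at 2.3 Gy. On day 3 they ran between 6931 and 11935 at 1.7 Gy, 690 and 4902 at 1.9 Gy, 5642 and 8973 at 2.1 Gy, and 5933 and 9484 at 2.3 Gy, and on day 7 between 265 and 2620 at 1.7 Gy, 177 and 802 at 1.9 Gy, 461 and 3112 at 2.1 Gy, and 1547 and 9112 at 2.3 Gy. At 1.9 Gy on day 3, 2 of 32 label swaps, the true labels among them, reached the count, so the size of the response is not compared between doses by these counts.

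The up and down split of single dose groups depended on the scaling. On day 1 quantile normalization gave 535 up and 568 down at 1.9 Gy, normexp 832 and 823 and the deposited values 664 and 754, and at 2.3 Gy normexp gave 1240 and 1719 and the deposited values 1140 and 1751. On day 3 quantile normalization, normexp and the deposited values gave 4277 and 3852, 3517 and 3557, and 3700 and 4683 at 1.7 Gy, and 3301 and 2861, 3495 and 2378, and 3520 and 3218 at 2.1 Gy. At 2.3 Gy on day 3 quantile normalization gave 4722 and 3206. On day 7 quantile normalization, normexp and the deposited values gave 641 and 194, 599 and 339, and 636 and 297 at 1.7 Gy, and 1995 and 1041, 1857 and 1697, and 1761 and 1531 at 2.3 Gy. At 1.9 Gy on day 7 normexp gave 637 and 257 and the deposited values 826 and 324, and at 2.1 Gy normexp gave 1189 and 814.

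Granule genes of immature neutrophils were the only list called for a dose slope, on day 1. Its mean change was 0.29 ± 0.36 (SD, n = 6) at 1.7 Gy, 0.38 ± 0.31 at 1.9 Gy, 0.82 ± 0.35 at 2.1 Gy and 0.99 ± 0.29 at 2.3 Gy, with 4, 5, 6 and 6 of 6 animals up. The slope over all 24 animals was 1.26 per Gy (permutation p = 0.00035, adjusted p = 0.0210 over 60 tests), with 0.82 in batch 1 and 1.70 in batch 2. LCN2, a member of that list, was among the genes with the smallest p-values, with slopes of 2.78 ± 0.84 per Gy on day 1 (limma unadjusted p = 0.00152) and 3.74 ± 0.81 on day 7 (limma unadjusted p = 2.2e-05, adjusted p = 0.368). On day 3 the slope of the list was 1.23 per Gy (permutation p = 0.0294, adjusted p = 0.277; batches 0.10 and 2.37) and on day 7 it was 1.1 (permutation p = 0.0239, adjusted p = 0.277; batches 0.87 and 1.33). The list holds CELA2A, placed there through an alias of neutrophil elastase although the symbol is that of a pancreatic elastase, and without it the day 1 slope was 1.32 per Gy (permutation p = 0.00053; batches 0.88 and 1.76).

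**Figure D3:**
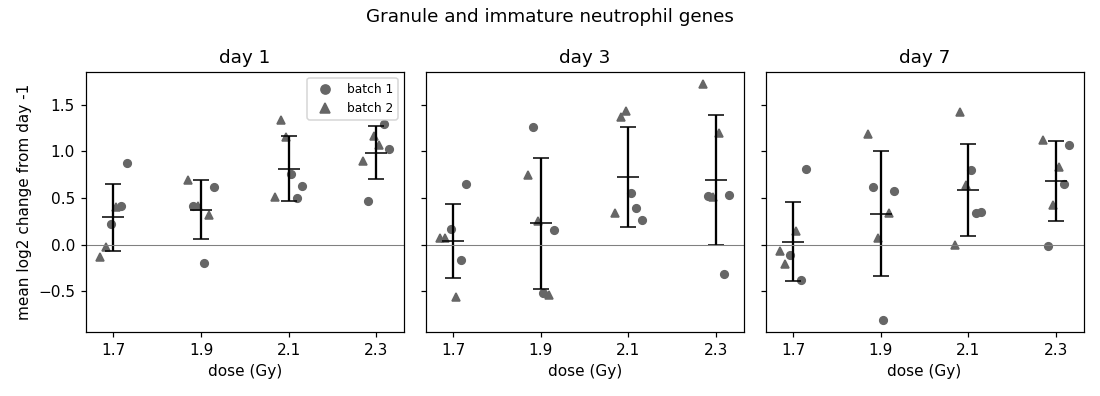
Mean log2 change of the granule and immature neutrophil genes against the sample before irradiation (vertical axis) by dose in Gy (horizontal axis) on days 1, 3 and 7. Each point is an animal, circles for batch 1 and triangles for batch 2, and the bars give the mean and SD of 6 animals.

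No single gene was called for a dose slope on any day with limma (0 of 33039, with 1162, 1783 and 1398 at an unadjusted p below 0.05 on days 1, 3 and 7). An F test over the 4 doses also gave 0 (462, 1004 and 2170 unadjusted), as did 2.3 Gy minus 1.7 Gy (1417, 1832 and 933 unadjusted), but array quality weights gave 1283 calls on day 1, or 597 when estimated gene by gene, a setting added after seeing the data. Apart from LCN2, the genes with the smallest p included TNIP1, a brake on NF-kB signalling, MUC20, a membrane mucin, ARF3, a GTPase of vesicle transport, and NANS, an enzyme of sialic acid synthesis, on day 1. On day 3 they were CEND1, a neuronal cell cycle protein, TNIP1, LMNA, a protein of the nuclear envelope, PAQR7, a progesterone receptor, and CCL3L1. On day 7 they were ACACB, an enzyme of fatty acid metabolism (3.6 ± 1.00 per Gy, limma unadjusted p = 0.000593), C4BPA, a complement inhibitor, PMAP-23, an antimicrobial peptide, and ANKRD6, a protein of Wnt signalling. The exact comparison of the granule list between 2.3 and 1.7 Gy on day 1 gave a difference of 0.69 (exact p = 0.01, adjusted p = 0.200). On day 1 complement and acute-phase genes, at 1.13 per Gy (permutation p = 0.00342, adjusted p = 0.103), and erythroid genes, at 1.28 per Gy (permutation p = 0.0105, adjusted p = 0.193), were not called, and no test separates the lists. Scan day equals dose in batch 1 and rises with dose in batch 2.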

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

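The tests of the signal floor, dilution, batch, slide position and scaling were chosen only after the results they concern had been seen. The test of vessel wall markers was chosen before its value was seen.

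In 15 of 248 groups of 6 animals, 1 animal lay far from the other 5, where by chance about 12.4 are expected. Animal 5507457 (2.1 Gy) lost fewer B cell transcripts on day 1, at -1.22 against -2.47 to -2.09 in the others. Animal 5506302 (1.7 Gy) had higher values on day 7 for NK and cytotoxic markers, at 1.77 (others -0.68 to 0.20), and for cell cycle genes, at 1.79 (others 0.07 to 0.63). Neutrophil markers on day 3 were at -0.96 in animal 5503346 (1.9 Gy; others 0.63 to 1.29). Dendritic cell markers on day 1 were at 0.42 in animal 5491062 (1.7 Gy; others -0.14 to -0.00) and at 0.27 in animal 5508020 (2.3 Gy; others -0.28 to -0.15), which on day 3 also had platelet genes at -0.50 (others 0.94 to 1.77). In animal 5489637 (2.1 Gy) interferon-stimulated genes were at 2.38 on day 3 (others -0.46 to 0.11) and cell cycle genes at 0.69 on day 7 (others 0.22 to 0.31). Animal 5492565 (1.9 Gy) stood at 1.51 for complement genes on day 1 (others 0.02 to 0.51) and at 0.25 for DNA repair genes on day 3 (others -0.08 to 0.04).

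Animal 5503117 (1.7 Gy) had interferon-stimulated genes at -1.32 on day 3 (others -0.12 to 0.09) and MHC class II genes at -0.005 on day 1 (others -0.55 to -0.40). Complement genes were at -0.28 on day 7 in animal 5501815 (1.7 Gy; others 0.04 to 0.23) and ribosomal protein genes at -0.061 on day 3 in animal 5493766 (2.1 Gy; others -0.76 to -0.53).

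Differences between groups were found in the dose slope of the granule genes on day 1 (1.26 per Gy) and in 3 lists between days 3 and 7: B cell markers rose by 0.58, eosinophil, basophil and mast cell genes stood at -0.42 and platelet genes at -1.09. The change since irradiation also differed between batches, in 47 features on day 1 (8 higher and 39 lower in batch 2), 7149 on day 3 (6685 and 464) and 316 on day 7 (304 and 12).

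Day labels were swapped within animals to see how many calls other splits of the same arrays give. The true split gave the most calls for each day comparison, being the 1 of 100 splits to reach its count, and the highest other counts were 1 for day 1, 11422 for day 3, 7042 for day 7, 10491 for day 3 against day 1 and 2067 for day 7 against day 3. Why single splits call so many was not tested. For single doses the true split was the 1 of 32 to reach its count, with highest other counts on day 1 of 15, 133, 135 and 368 from 1.7 to 2.3 Gy, on day 3 of 5578 at 1.7 Gy, 3497 at 2.1 Gy and 6587 at 2.3 Gy, and on day 7 of 395, 161, 450 and 1352. At 1.9 Gy on day 3, 2 of 32 splits reached it, and the highest other count was 2790. For the dose slopes, which had 0 calls, 100 of 100 splits had as many, with highest counts of 0, 2 and 1426 on days 1, 3 and 7, and for the dose groups before irradiation 100 of 100 (highest 2). For the batches before irradiation the true split was the 1 of 100 to reach its count, with 8865 as the highest other.

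The excess of decreases among dim features on day 3 may come from a signal floor under the array scaling. Over 24 animals the scaled change of the dimmest set fell with the rise of the 75th percentile (Pearson r = -0.659, permutation p = 0.00052, adjusted p = 0.00078; Spearman rho = -0.583; -0.469 without the 2 farthest animals; -0.955 and -0.402 in the batches), and on day 7 likewise (-0.718; -0.987 and -0.245 in the batches). The scaled change contains the percentile with a negative sign by construction, so part of this relation is built in. Before scaling, the dimmest set rose by a median of 0.58 on day 3 while the percentile rose by 1.53, so the dim spots did not lose signal. No biological explanation was tested.

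The fall of B cell transcripts on day 1 is larger than dilution by RNA of other cells allows, since dilution would lower T cell markers as much. The B cell list fell further than the T cell list in 24 of 24 animals, by a mean difference of -1.60 ± 0.46 (SD) on day 1, -1.24 ± 0.57 on day 3 and -0.70 ± 0.53 on day 7 (22 of 24 animals). A single batch is also excluded, as the smaller of the batch means was -1.83. Slide position stays open, because each of the 4 days lies at a fixed position.

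The rise of platelet transcripts on day 3 does not come from the scaling, since the list stood at 1.16 above all features with quantile normalization. Whether RNA of the vessel wall, taken up at the blood draw, added to it stays open. Endothelial markers stood at -0.018 above all features on day 3, a value that the prediction written beforehand had set as evidence against it, but the question was left open after seeing that only 2 of the 4 markers, VCAM1 and ENG, were well above background on at least 12 arrays. These moved apart, VCAM1 at 0.66 ± 0.20 and ENG at -0.49 ± 0.17.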

How the results depend on the processing

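The alternatives were planned before the data were examined, except the common floor, the omission of 2 animals with a doubted array, the gene by gene weights and the granule list without CELA2A, which were chosen only after the results had been seen.

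Of 43 list calls, 7 were lost with quantile normalization, and 8 each with normexp, the deposited values and the filter of 48 arrays. Batch 1 alone lost 5, batch 2 alone 7, the common floor 4, and fry, no filter and all probes kept 1 each. An estimated correlation lost 32. The median shift of the ribosomal list turned to 0.172 on day 3 and 0.16 on day 7 in batch 1, and to 0.057 on day 7 with no filter, where the call stayed. Lists called only under an alternative numbered 3 with each of the other scalings, 5 in batch 1, 8 with fry, 3 with the common floor, 2 with all probes kept, and 1 each with no filter, without the animal block and with batch by day terms. Of 291 values of named genes, 10 lost their call with quantile normalization, 18 with normexp, 13 with the deposited values, 23 without the animal block, 8 with a random effect and 5 without the 2 animals, while 8, 6 and 12 gained it with the 3 scalings. MUC20 on day 3 turned to 0.031 with quantile normalization, and RPLP0 on day 7 turned to 0.111, 0.066 and 0.125 with quantile normalization, normexp and the deposited values. Where a cause is not named below, the cause was not tested.

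Quantile normalization gave 337 calls at 1.7 Gy and 1103 at 1.9 Gy on day 1, 835, 1043 and 3036 at 1.7, 1.9 and 2.3 Gy on day 7, and 44 between dose groups before irradiation. With normexp the counts were 446, 1655 and 2959 at 1.7, 1.9 and 2.3 Gy on day 1, 7074 at 1.7 Gy on day 3, 938 and 3554 at 1.7 and 2.3 Gy on day 7, and 6 before irradiation. With the deposited values they were 420, 1418 and 2891 at 1.7, 1.9 and 2.3 Gy on day 1, 2854 at 1.9 Gy on day 3, 933, 1150 and 3292 at 1.7, 1.9 and 2.3 Gy on day 7, 94 between dose groups before irradiation and 0 between batches, whose difference that table hardly holds (SD over probes 0.04).

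Without the filter on dim probes 12555 and 13517 features were called at 2.1 and 2.3 Gy on day 3 and 13794 at 2.3 Gy on day 7, with more features tested. With the filter of 48 arrays, which tests fewer features, the counts were 11823 on day 3 (6573 up and 5250 down), 11302 between days 1 and 3, 328 and 926 at 1.7 and 1.9 Gy on day 1, 6997 at 1.7 Gy on day 3, 986 and 4728 at 1.9 and 2.3 Gy on day 7, 3 between dose groups before irradiation and 8489 between batches. A minimum of 2-fold, which is stricter by construction, left 607, 6251 and 1194 on days 1, 3 and 7, 5237 and 648 for the steps to days 3 and 7, 306, 1008 and 929 at 1.9, 2.1 and 2.3 Gy on day 1, and 1130 and 380 at 1.9 Gy on days 3 and 7.

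Without the animal block, which drops the pairing of the arrays of an animal, 63, 112, 503 and 462 features were called at the 4 doses on day 1, 305 and 4968 at 1.9 and 2.1 Gy on day 3, 110, 71, 270 and 2906 on day 7, and 2387 between days 3 and 7. Batch by day terms in the block gave 2421 at 1.7 Gy on day 7. With animals as a random effect 296 and 328 were called at 1.9 Gy on days 1 and 7. Using only the 12 arrays of a comparison, with fewer samples for the spread, gave 82, 12 and 751 at 1.7, 1.9 and 2.3 Gy on day 1, 18 and 1540 at 1.9 and 2.3 Gy on day 3, and 4233, 0 and 83 at 1.7, 1.9 and 2.1 Gy on day 7. Batch 1 alone gave 1976 on day 1 and batch 2 alone 6436 on day 7, each with 12 animals.

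Array quality weights in the block gave 1283 and 7 dose slopes on days 1 and 7, 2157, 3550, 4938 and 6126 calls at the 4 doses on day 1, 7814 and 12383 at 1.9 and 2.1 Gy on day 3, and 8756, 1946 and 6207 at 1.7, 1.9 and 2.1 Gy on day 7. Their estimation did not reach its tolerance, with weights from 0.12 to 58.2. Gene by gene weights (0.14 to 5.18) gave 597 dose slopes on day 1, 1773, 3065, 4488 and 5880 calls at the 4 doses on day 1, 7413 at 1.9 Gy on day 3, and 8490, 1900 and 5771 at 1.7, 1.9 and 2.1 Gy on day 7. The comparisons before irradiation were not run with weights. A slide or scan day block was not run, because the animal block already holds the slide for 23 of 24 animals.

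With the common floor, which sets 70.9% of the values to a constant, 3725, 6503 (4554 up and 1949 down) and 4052 features were called on days 1, 3 and 7, 6099 and 1761 for the steps to days 3 and 7, 3 dose slopes on day 7 and 2702 between batches. By dose the counts were 116 and 1069 at 1.7 and 2.1 Gy on day 1, 2401, 942, 2662 and 4228 on day 3, and 441, 848 and 1738 at 1.7, 2.1 and 2.3 Gy on day 7. Without the 2 animals they were 5527 at 1.9 Gy on day 3, 3258 at 1.7 Gy on day 7, 1 dose slope on day 3 and 128 between dose groups before irradiation.

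Leaving out each animal in turn gave 5780 to 6762 calls on day 1, 17732 to 19674 on day 3 and 10875 to 15402 on day 7, and 0 to 0, 0 to 0 and 0 to 1 dose slopes (1 without animal 5493758). On day 1 the counts ran from 109 to 239 at 1.7 Gy, 239 to 684 at 1.9 Gy, 978 to 1975 at 2.1 Gy and 724 to 1980 at 2.3 Gy. They fell to 117, 111, 126, 126 and 109 without 5491062, 5491551, 5501815, 5503117 and 5507236 at 1.7 Gy, to 340, 239 and 296 without 5490775, 5493112 and 5507384 at 1.9 Gy, to 1022, 978 and 1116 without 5491003, 5493766 and 5502145 at 2.1 Gy, and to 724, 724 and 1101 without 5502439, 5503036 and 5508305 at 2.3 Gy. On day 3 they ran from 6931 (without 5506302) to 11935 at 1.7 Gy, 690 to 4902 at 1.9 Gy, 5642 to 8973 at 2.1 Gy and 5933 to 9484 at 2.3 Gy, with 885, 4902, 967, 1078 and 690 at 1.9 Gy without 5490775, 5492565, 5493112, 5503532 and 5507384. On day 7 they ran from 265 to 2620 at 1.7 Gy, 177 to 802 at 1.9 Gy, 461 to 3112 at 2.1 Gy and 1547 to 9112 at 2.3 Gy. The animals behind these were 5491062, 5491551, 5492565, 5501815, 5506302 and 5507236 (599, 921, 2620, 502, 330 and 265) at 1.7 Gy, 5490775, 5503532 and 5507384 (236, 235 and 177) at 1.9 Gy, 5489637 and 5491003 (780 and 461) at 2.1 Gy, and 5493758, 5508020 and 5508305 (4272, 1547 and 4311) at 2.3 Gy.

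Signal over background limits the dim features, as a median of 21712 of 43803 spots per array stood clear of it.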

Other observations

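The lists of vessel wall and matrix genes given here were chosen only after the platelet result had been seen.

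Of 7 fibroblast and matrix genes, whose products build connective tissue, COL1A2 rose on day 3 by 1.37 ± 0.46 (well above background on 5 of 24 arrays before and 18 of 24 then) and DCN fell by 1.13 ± 0.26. The list stood at 0.27, 0.21 and -0.07 above all features on days 1, 3 and 7 and was not called by camera on any of them. Of 4 endothelial markers VCAM1, an adhesion molecule for leukocytes, rose by 1.18 ± 0.20 on day 7 while ENG, a receptor of vessel lining, fell by 0.57 ± 0.17, and the list stood at 0.11, -0.02 and -0.17.

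The pre-irradiation array of animal 5492336 (2.3 Gy) lies on another slide than that animal's other 3. The day 1 array of animal 5492565 (1.9 Gy, batch 1) had 31171 spots well above background, where the median of its batch was 17147. Of 8 scan days, 5 hold a single dose and 3 hold 2 doses.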
